A study of Mus musculus with 8 samples.

How the data were processed

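Dorsal skin of 3-month-old wild-type mice and of mice carrying a knockout of Tph1 was profiled by bulk RNA-seq, with 4 libraries of each genotype. Tph1 encodes the tryptophan hydroxylase that carries out the rate-limiting step of serotonin synthesis outside the brain. Per the labels' protocols, total RNA was extracted with a column kit from Qiagen and libraries were made with the NEBNext Ultra RNA kit, which does not mark the strand of origin, so reads of a gene and of an overlapping antisense gene cannot be told apart. The submitters' processing notes name STAR 2.7.6a, RSEM 1.31, DESeq2 and DESeq and the mouse build GRCm38, with no role or order, and the labels name Ensembl release 101 as the annotation.

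Each library had its own deposited table of RSEM output with 55488 genes. The expected counts in these deposited tables are RSEM's estimates of the reads per gene, not normalized, and between 10.7% and 11.5% of the genes in a library held a value that was not whole. RSEM divides a read that matches several genes among them by probability, so counts of genes with near-identical copies depend on that division. The deposited TPM values are in RSEM units scaled to effective gene length and library size per the file headers, and were used only as an alternative scale for Tph1. The deposited FPKM values, per the file headers, are fragment counts scaled to gene length and library size and entered no test. Effective gene lengths from the deposited tables entered 1 alternative fit. The authors also deposited a matrix of 17382 genes whose values are a normalized signal, described in the labels as DESeq2-normalized. In 12301 genes compared, the ratio of the rounded count to the authors' value was within 1% of a single factor per library for only 27.8% to 37.6% of genes. After division by relative effective gene length it was within 1% for 100% of them in every library, so the authors' values carry a gene length correction per library. The filter that chose the matrix's genes is not given in the sources used here.

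Gene symbols came from the authors' matrix for 17354 identifiers and from a reference name table for 37798, and 336 identifiers had no symbol. Coordinates were taken from GENCODE release M21 on GRCm38, the build of the files, which held 16891 of the 16908 tested genes. Copies of Ftl1 were found by aligning its longest transcript to annotated transcripts with BLAST, with at least 85% identity over at least 400 bases. For processed pseudogenes, the parent gene was the protein-coding gene with the highest BLAST score, with no limit on identity or length.

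Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr by genotype (minimum count 10, minimum total 15), scaled by TMM, and compared between genotypes by the robust quasi-likelihood F test with genotype as the only term. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are knockout over wild type on the log2 scale, with a standard error (SE) equal to the size of the log2 fold change divided by the square root of F. CPM values are counts relative to the TMM-scaled library size, as edgeR gives them. Single values were compared by an exact permutation test, two-sided, over the 70 assignments of 8 libraries to 4 and 4, which cannot give a p below 0.0286. The replicate numbers follow the order of the records and pair no libraries, and the labels give no batch, litter or sex. The labels do not say that each library came from a different mouse, so p-values measure the spread between these libraries.

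Before the data were examined, 43 gene lists were written for skin layers, hair, dermal matrix, fat, other cell types, RNA quality, handling of the tissue and genes beside Tph1. Of these, 42 had at least 3 tested members. Each was tested against the other genes with camera (limma 3.58.1, preset correlation 0.01), with Benjamini-Hochberg adjustment over 42 lists, and again with an estimated correlation between members. Each list was also tested with fry, which tests its members against no change and not against the other genes. The level of a list in a library is the mean over its members of log2(CPM + 1). Counts of called members are given over all genes tested and adjusted over the list alone. The genes named were also fixed by rule. They are Tph1, then the 12 largest rises and 12 largest falls among called genes with a mean CPM of at least 1 and all 4 knockout libraries on one side of all 4 wild-type libraries. Predicted genes, clones, immunoglobulin and T cell receptor segments and pseudogenes were left out of those 24. From each list up to 4 members with the smallest p followed, then further list members as examples that did not pass. Of the genes that the rule names, 2 are not reported here, though they stay in every test and count but the search for libraries far from their group. Genes named outside the rule are said to have been chosen after their values were seen.

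On simulated counts for 16577 genes with the means and dispersions of these libraries, the test of knockout against wild type recovered 43% of 100 genes changed by 1 on the log2 scale. It recovered 91% of 100 genes changed by 2, and 10 of its 144 calls were false. The changed genes were drawn from those with a mean CPM of at least 1. Counts were simulated for each gene independently, unlike in these libraries, where genes vary together. The list test found 3 of 3 simulated shifted lists and called 0 others, and it called 1 list in a simulation with no shifted list. On the real counts, splits of the libraries that mixed the genotypes called a median of 18 lists and at most 32. The simulation therefore does not show how often the list test calls lists wrongly in these libraries. Total expected counts ranged from 20531600 to 24678600 per library. For Tph1, counts carry exact Poisson 95% intervals and a floor of 3 counts, which cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of the 28 library pairs agreed within sampling noise (chi-square per degree of freedom at least 33.0), so each library counted as 1 replicate.

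The alternatives were DESeq2 median-ratio and upper quartile scaling, TMM without the genes of hair, muscle, fat, blood and mitochondria, no filter and a filter of 1 CPM in 4 libraries. Others were the DESeq2 1.42.0 Wald test, limma-voom, limma on the authors' matrix, no robust fit, 1 surrogate variable (sva 3.50.0), and the level of hair, skeletal muscle or adipocyte genes as a covariate. Thresholds of 0.1 and of a fold of at least 1.5, pseudocounts of 0.5 and 5, other windows around Tph1 and leaving out each library completed the set. A handling covariate, effective length offsets, a fit without the genes around Tph1 and copies of Ftl1, and a fit without 2 libraries in doubt were added after seeing the data. The list of sex-linked genes was used only as a check: all 8 libraries had 0 counts for the 4 Y-linked genes and between 6572 and 16461 counts for Xist.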

Results

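The series compared dorsal skin from 3-month-old wild-type mice with dorsal skin from Tph1 knockout mice, to ask how loss of peripheral serotonin synthesis affects the epidermis and dermis. Bulk RNA-seq gave 4 wild-type and 4 knockout libraries with 20531600 to 24678600 expected counts each. The mean total was 22.9 M ± 1.73 (SD, n = 4) in wild type and 23.1 M ± 1.51 (SD, n = 4) in knockout (exact permutation p = 0.743). Of 29559 genes with any count, 16908 passed the filter on low counts and were tested.

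Tph1 (ENSMUSG00000040046), on the minus strand of chromosome 7 from 46644641 to 46672537 in GRCm38, was barely expressed in wild-type skin and had no counts in knockout skin. The wild-type libraries held 18, 0, 27 and 11 counts and each of the 4 knockout libraries held 0, where the floor of 3 counts corresponds to 0.125 to 0.139 CPM per library. The wild-type mean was 0.597 ± 0.501 CPM (SD, n = 4). The 56 counts of the pooled wild-type libraries, per pooled library size, were at least 18.1-fold above the floor of 3 counts over the pooled knockout libraries. The wild-type library without a Tph1 count, replicate 2, left the genotypes overlapping (exact permutation p = 0.143), and the gene was too low for the filter. Without that library the p was 0.0286, the smallest that 3 against 4 libraries can give. In other respects wild type replicate 2 resembled the other wild-type libraries at this locus. Only 3.01% of its counts for Ftl1 and its copies fell on the copies, against 3.14% to 3.53% in the other wild-type libraries and 79.0% to 81.1% in knockout libraries.

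Other genes of serotonin handling did not pass the test. Of 24 listed genes for synthesis, transport and receptors, 7 were expressed enough to test, with a median log2 fold change of 0.24 (camera adjusted p = 0.652). Without 1 library the median of this serotonin list ran from -0.090 to 0.20 and was negative in 3 of 8 fits. The serotonin transporter Slc6a4 was measured at 31.3 ± 10.1 CPM (SD, n = 4) in wild type and 37.0 ± 10.9 in knockout (log2 fold change 0.25 ± 0.26 SE, edgeR adjusted p = 0.642). The gene of the degrading enzyme Maoa had a log2 fold change of -0.23 ± 0.12 (SE, edgeR adjusted p = 0.340). The receptor gene Htr1b was at 0.261 ± 0.188 CPM in wild type and 0.650 ± 0.0475 in knockout (SD, n = 4 each, edgeR adjusted p = 0.226).

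Knockout skin differed from wild type in 110 genes, of which 90 were lower and 20 higher (edgeR quasi-likelihood test, adjusted p under 0.05) and 10 of the lower genes were among the 113 tested members of the spinous, granular, barrier lipid and junction lists. At an unadjusted p under 0.05 there were 2981 genes. In 1867 genes, 11% of those tested, all 4 knockout libraries lay on one side of all 4 wild-type libraries. Over random assignments this share averages 2.86%. Genes vary together between libraries, so a single assignment can lie far from that average, and the share was not computed for other assignments. The number of calls varied with the libraries used. It was 26, 88, 32 and 27 without wild type replicates 1 to 4 and 19, 8, 170 and 14 without Tph1 knockout replicates 1 to 4. It was 167 without both libraries in doubt, wild type replicate 2 with no Tph1 count and Tph1 knockout replicate 3 with the highest hair gene level. The DESeq2 Wald test called 984 genes on the same counts, including all 110. The 37 genes of the naming rule that passed kept their direction under every alternative in which they were tested.

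Among genes that the naming rule allows, which leaves out predicted genes and pseudogenes, the largest rises were in Ush1c, which encodes the scaffold protein harmonin (log2 fold change 4.68 ± 0.61 SE), Zfp473, a zinc finger gene (2.32 ± 0.38), and Scube2, which encodes a secreted protein (1.38 ± 0.22). Fgf1, a growth factor gene, rose from 27.1 ± 3.16 to 50.7 ± 4.97 CPM (SD, n = 4 each), with a log2 fold change of 0.90 ± 0.13 (SE, edgeR adjusted p = 0.0220). Cdkn1b, which encodes the cell cycle inhibitor p27, rose by 0.87 ± 0.16 (SE) on the log2 scale. The other rises named by the rule were Angptl7, Papln, Cpt1c, St3gal5, Tubgcp5, Trim23 and Megf6, with log2 fold changes of at least 0.74, the value of Megf6. Under the same rule the largest fall was in Arc, an immediate early gene (-3.90 ± 0.67 SE), followed by Htatip2 (-3.59 ± 0.40), the ferritin light chain gene Ftl1 (-2.73 ± 0.18) and the mast cell receptor gene Mrgprb2 (-2.52 ± 0.31). The immediate early genes Csrnp1 (-2.40 ± 0.41) and Nr4a1 (-2.18 ± 0.33) also fell, as did Plac9b, Ly6m, Ifitm6, the lipid transporter gene Mfsd2a, Fut2 and Sfn. Sfn, which encodes the keratinocyte protein 14-3-3 sigma, was at 1372 ± 670 CPM (SD, n = 4) in wild type and 380 ± 68.9 in knockout (-1.85 ± 0.34 SE, edgeR adjusted p = 0.0487). Sfn was called in only 1 of 8 fits without 1 library and under 1 of 3 other scalings, and with the level of immediate early and heat shock genes as a covariate it was at -0.68 (adjusted p = 0.663). Under that covariate Arc, Csrnp1 and Nr4a1 were at -0.93, -0.67 and -1.08 (edgeR adjusted p = 0.694, 0.674 and 0.619). Nr4a1 is a member of the list behind that covariate, so its value moves toward no change partly by construction. Among these 24 genes, Ush1c, Zfp473, Cpt1c, Tubgcp5, Htatip2, Ftl1, Mrgprb2 and Fut2 lie within 10 Mb of Tph1. In fits that left out 1 library, only Ftl1 and Gjb5 of the 37 genes of the naming rule that passed were called in all 8, and St3gal5, Megf6 and Gtf2h1 were called in 0. Of the 37, 32 were called under all 3 other scalings.

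The lists of spinous and granular layer genes were called lower by camera but not with an estimated correlation (adjusted p = 0.534 and 0.472), and the list of basal genes was not called. Of 19 genes of the spinous layer, 3 fell and 16 did not pass, with 10 lower when adjusted over the list alone and a median log2 fold change of -0.55. Calm4, a calmodulin-like gene of differentiating keratinocytes, fell from a mean of 509 to 175 CPM (n = 4 each; -1.54 ± 0.21 SE, edgeR adjusted p = 0.0202). Krtdap, a gene of keratinocyte differentiation that lies within 20 Mb of Tph1, fell from 1167 ± 257 to 451 ± 58.1 CPM (SD, n = 4 each; -1.37 ± 0.21 SE), and the keratin gene Krt78 fell from 92.7 ± 4.43 to 43.0 ± 8.95 CPM (-1.11 ± 0.15). Suprabasin, Sbsn, was at 2086 ± 36.9 CPM in wild type and 944 ± 239 in knockout without passing (adjusted p = 0.0632), and Krt10, the main spinous keratin gene, had a log2 fold change of -0.96 ± 0.35 (SE). Of 42 genes of the granular layer and cornified envelope, 3 fell and 39 did not pass, with 18 lower when adjusted over the list alone and a median of -1.03. Lor, which encodes loricrin, the main protein of the cornified envelope, fell from 2212 ± 241 to 799 ± 220 CPM (-1.47 ± 0.24 SE, edgeR adjusted p = 0.0379). Crct1 fell by 1.40 ± 0.22 (SE) on the log2 scale, and the protease gene Klk8, which lies within 10 Mb of Tph1, fell by 1.25 ± 0.20. Filaggrin, Flg, and involucrin, Ivl, had log2 fold changes of -0.97 ± 0.32 and -1.28 ± 0.40 (SE) and did not pass (adjusted p = 0.188 and 0.166).

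**Figure D1:**
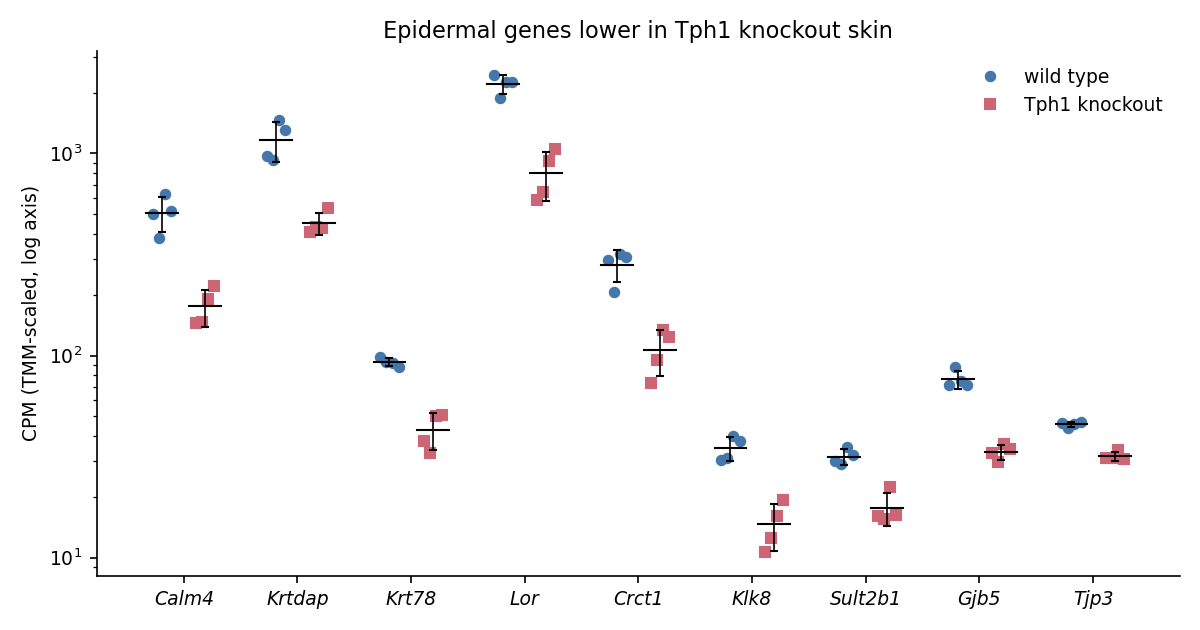
CPM on a log axis for 9 of the 10 genes of the spinous, granular, barrier lipid and junction lists that fell, with 1 point per library, circles for wild type and squares for Tph1 knockout and black bars for the mean and SD of 4 libraries. All 4 knockout points of each gene lie below all 4 wild-type points, as in Lor, with means of 2212 and 799 CPM.

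By camera the spinous and granular lists were lower than other genes (adjusted p = 2.36e-09 and 7.98e-18). Neither call held with an estimated correlation between members, as given above. The mean list level differed by -0.63 for spinous genes (7.93 ± 0.28 SD against 7.30 ± 0.48 SD, n = 4 each, exact permutation p = 0.114) and by -0.87 for granular genes (5.57 ± 0.53 against 4.71 ± 0.22, exact permutation p = 0.0857). The granular call was also lost with the level of immediate early and heat shock genes as a covariate, called the handling covariate here, where the median was 0.03 (adjusted p = 0.142). Of 16 basal keratinocyte genes, 0 were called, with a median of -0.12 (-0.25 to -0.014 without 1 library; camera adjusted p = 0.779). The basal keratin genes Krt5 and Krt14 had log2 fold changes of -0.33 ± 0.34 and -0.52 ± 0.39 (SE). Of 30 cell proliferation genes 0 were called, with a median of -0.23 (camera adjusted p = 0.0283, and adjusted p = 0.874 with an estimated correlation). The proliferation call was lost without wild type replicate 3 or 4 or Tph1 knockout replicate 3 or 4, with medians of -0.10, -0.21, -0.17 and -0.18. It was also lost with 1 surrogate variable as a covariate (-0.22, adjusted p = 0.0623), with muscle, adipocyte or handling level as a covariate (-0.091, -0.20 and 0.090, adjusted p = 0.651, 0.106 and 0.595), and without both libraries in doubt (-0.28, adjusted p = 0.0701).

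Of 29 barrier lipid genes, 1 fell, with 6 lower when adjusted over the list alone and a median of -0.41 (camera adjusted p = 1.90e-07, and adjusted p = 0.827 with an estimated correlation). The gene that fell was Sult2b1, a cholesterol sulfotransferase gene within 10 Mb of Tph1 (-0.85 ± 0.15 SE). The lipoxygenase gene Alox12b and the fatty acid elongase gene Elovl1 were at -1.49 ± 0.28 and -1.09 ± 0.21 without passing (adjusted p = 0.0538 and 0.0547). Of 23 junction genes, 3 fell, with 11 lower when adjusted over the list alone and a median of -0.43 (camera adjusted p = 2.02e-07, and adjusted p = 0.534 with an estimated correlation). The connexin gene Gjb5 fell from 76.3 ± 7.73 to 33.4 ± 2.81 CPM (SD, n = 4 each; -1.19 ± 0.12 SE, edgeR adjusted p = 0.00363), and it was called in every alternative. The tight junction gene Tjp3 fell by 0.52 ± 0.09 (SE) on the log2 scale. Of 10 stress keratin and alarmin genes, 0 were called, with a median of -0.69 (camera adjusted p = 0.0253, and adjusted p = 0.827 with an estimated correlation). The call on stress keratins and alarmins was lost without wild type replicate 1 or 3 or Tph1 knockout replicate 1, where the medians were -0.72, -0.53 and -0.71. It was also lost with the muscle covariate (-0.44, adjusted p = 0.491) and the handling covariate (-0.12, adjusted p = 0.548).

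The list of extracellular calcium and vitamin D handling in epidermis includes transcription factors of late differentiation. Of 30 members, 1 fell and 14 were lower when adjusted over the list alone, with a median log2 fold change of -0.54 (camera adjusted p = 2.53e-08). The median was -0.27 with the handling covariate (camera adjusted p = 0.000270). The adjusted p was 0.104 with an estimated correlation. By fry, which tests a list against no change and not against other genes, it was 0.00826, the only fry call among 42 lists. The list level was 6.41 ± 0.06 (SD, n = 4) in wild type and 6.02 ± 0.05 in knockout, with every knockout library below every wild-type library (exact permutation p = 0.0286, adjusted p = 0.429 over 42 lists). Cebpb, which encodes a transcription factor of keratinocyte differentiation, fell from a mean of 132 to 75.7 CPM (-0.81 ± 0.13 SE, edgeR adjusted p = 0.0324). The differentiation factor gene Grhl3 was at -1.25 ± 0.25, the calcium channel gene Orai1 at -0.58 ± 0.11 and S100a4 at -0.96 ± 0.20 (SE), with adjusted p = 0.0646, 0.0596 and 0.0671.

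Lists of tissue handling, muscle, mitochondrial and ribosomal protein genes were called by camera with the preset correlation only. Of 28 immediate early and heat shock genes, 1 fell, Nr4a1, and 20 were lower when adjusted over the list alone, with a median of -1.28 (camera adjusted p = 3.98e-18, and adjusted p = 0.470 with an estimated correlation). The list level was 7.82 ± 0.68 (SD, n = 4) in wild type and 6.60 ± 0.31 in knockout (exact permutation p = 0.0571). All 31 skeletal muscle genes had positive log2 fold changes and 0 were called, with a median of 0.59 (camera adjusted p = 6.18e-07, and adjusted p = 0.827 with an estimated correlation). The muscle median was 0.99 without wild type replicate 2, 0.28 without wild type replicate 3 and 0.39 without Tph1 knockout replicate 4. The muscle list level was 8.65 ± 0.99 in wild type, where it ranged from 7.36 to 9.48, and 9.62 ± 0.25 in knockout (n = 4 each, exact permutation p = 0.0857). All 13 mitochondrially encoded genes were also positive and 0 were called, with a median of 0.81 (camera adjusted p = 1.55e-07, and adjusted p = 0.630 with an estimated correlation). All genes with the symbol prefix mt-, not only these 13, took 5.98% ± 1.89 of counts (SD, n = 4) in wild type and 9.32% ± 1.36 in knockout (exact permutation p = 0.0571). Of 88 members of the cytosolic ribosomal protein list, 87 had negative log2 fold changes and 1 was called. The called member was Rps4l, which is annotated as a transcribed processed pseudogene, and no protein-coding member was called. The list had a median of -0.42 (camera adjusted p = 1.25e-14, and adjusted p = 0.827 with an estimated correlation). With muscle, adipocyte or handling level as a covariate the number of called genes was 6, 8 and 5. The 90 members of the spinous, granular and barrier lipid lists had a median log2 fold change of -0.82 with the adipocyte level as a covariate. It was -0.99 with the hair level and -0.97 with 1 surrogate variable. The median was -0.87 without a covariate, -0.42 with the muscle covariate and -0.28 with the handling covariate. For the 10 called epidermal genes it was -1.22, -1.22 and -1.21, with a median SE of 0.18, 0.21 and 0.30. Only 1 of the 10, Gjb5, was called under either covariate. The 10 were chosen because they passed without a covariate, so their steady median does not weigh against either covariate.

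**Figure D2:**
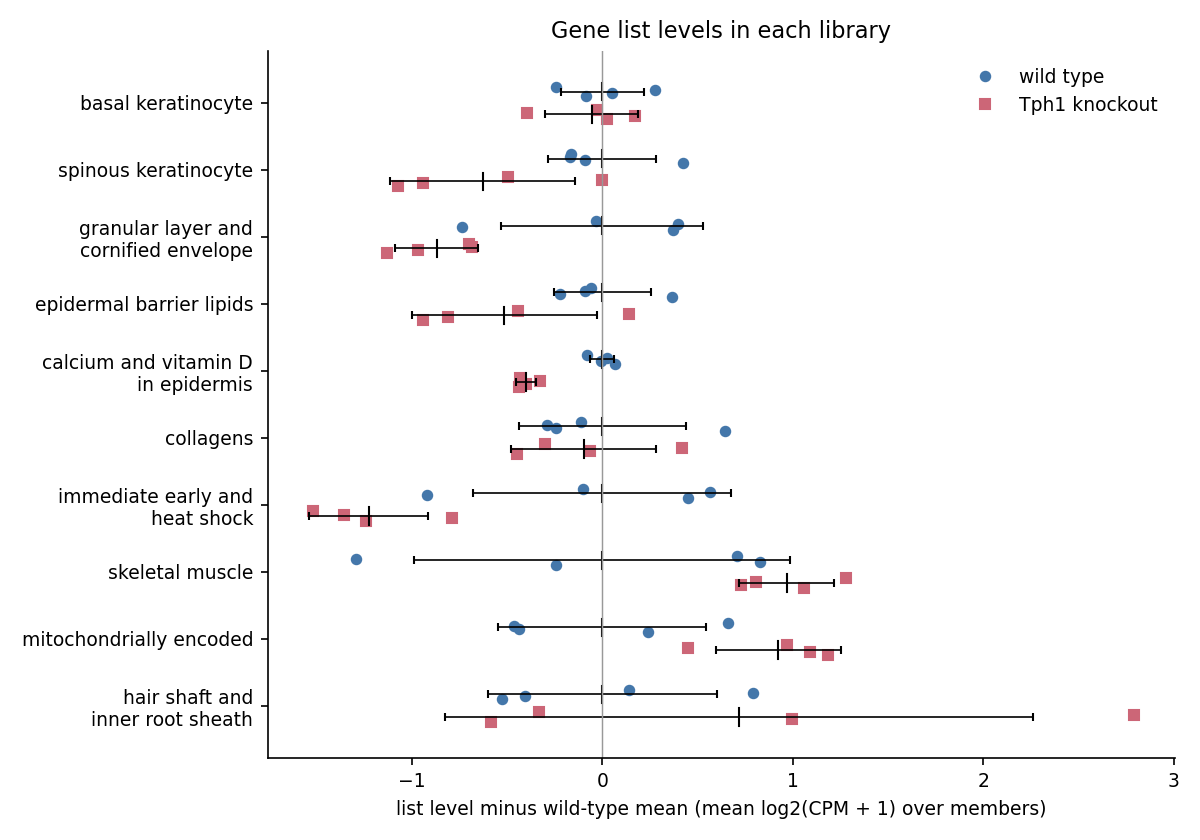
Level of 10 gene lists in each library, as the mean log2(CPM + 1) over members minus the wild-type mean, with circles for wild type and squares for Tph1 knockout and black lines for the mean and SD of 4 libraries. The calcium and vitamin D list separates the genotypes, while the granular, immediate early and muscle lists overlap through wild type replicate 2.

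No gene of the dermal lists was called, while camera called the lists of matrix proteases and fibroblasts lower. Of 22 collagen genes, 28 collagen processing genes, 19 elastic fibre genes and 38 proteoglycan and matricellular genes, 0 were called, with medians of -0.15, -0.06, -0.12 and -0.03 (camera adjusted p = 0.769, 0.376, 0.918 and 0.918). Each of these medians had either sign when 1 library was left out, from -0.41 to 0.055, -0.24 to 0.072, -0.30 to 0.17 and -0.31 to 0.36. Col1a1 and Col3a1, the main dermal collagen genes, were at 370 ± 368 and 410 ± 320 CPM (SD, n = 4) in wild type and at 152 ± 95.6 and 206 ± 104 in knockout (edgeR adjusted p = 0.311 and 0.327). The wild-type spread came from wild type replicate 1, the highest for both genes. Of 26 genes of TGF-beta signalling and myofibroblasts 0 were called, with a median of -0.02 (-0.076 to 0.13 without 1 library; camera adjusted p = 0.779). Of 29 matrix protease and inhibitor genes 0 were called, with a median of -0.43 (camera adjusted p = 0.00148, and adjusted p = 0.827 with an estimated correlation). Of 25 fibroblast genes 0 were called, with a median of -0.40 (camera adjusted p = 0.00760, and adjusted p = 0.827 with an estimated correlation). Both calls were lost without wild type replicate 1 (medians -0.15 and -0.29), and the fibroblast call also without Tph1 knockout replicate 4 (-0.26). Both were also lost with the muscle covariate (matrix proteases -0.21 and fibroblast -0.066, adjusted p = 0.205 and 0.521), the adipocyte covariate (-0.24 and -0.15, adjusted p = 0.0977 and 0.239) and the handling covariate (0.16 and 0.30, adjusted p = 0.607 and 0.142). The dermal lists depended on the libraries and covariates. Without both libraries in doubt the collagen and proteoglycan lists were called lower (medians -0.44 and -0.32, camera adjusted p = 0.0403 and 0.0178), and with the handling covariate the elastic fibre and proteoglycan lists were called higher (medians 0.42 and 0.64, camera adjusted p = 0.0445 and 0.00257).

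Lipid genes outside the barrier list gave a call for cholesterol synthesis and adipocytes. Of 23 cholesterol synthesis genes 0 were called, with 6 lower when adjusted over the list alone and a median of -0.36 (camera adjusted p = 5.49e-05, and adjusted p = 0.827 with an estimated correlation). The median was -0.20 without wild type replicate 1 or Tph1 knockout replicate 2 and -0.63 without Tph1 knockout replicate 3. Examples were Ebp at -0.50 ± 0.11 and Dhcr7 at -0.63 ± 0.17 (SE), with edgeR adjusted p = 0.0879 and 0.124. Of 24 adipocyte genes 0 were called, with a median of -0.50 (camera adjusted p = 0.0269, and adjusted p = 0.836 with an estimated correlation), and that call was lost without wild type replicate 4 or Tph1 knockout replicate 1 or 4 (medians -0.51, -0.30 and -0.22), while the median was -0.32 without wild type replicate 3 and -0.77 without Tph1 knockout replicate 2. The adipocyte call was also lost with the surrogate variable (-0.55, adjusted p = 0.0750) and the muscle and handling covariates (-0.16 and 0.076, adjusted p = 0.112 and 0.868), and by construction with the adipocyte covariate. Of 20 fatty acid and triglyceride synthesis genes and 10 thermogenic adipocyte genes 0 were called, with medians of 0.01 and 0.22 (camera adjusted p = 0.918 and 0.832), and from -0.30 to 0.14 and from -0.096 to 0.40 without 1 library.

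Genes beside Tph1 on chromosome 7 were called far more often than genes elsewhere. Within 10 Mb of Tph1, 15 of 186 tested genes were called (8.06%), against 95 of 16722 elsewhere (0.568%), an odds ratio of 15.3 (95% interval 8.09 to 27.3, Fisher's exact p = 1.12e-12). The 15 genes went both ways, with 5 higher and 10 lower. Without Tph1 knockout replicate 2, where only 8 genes were called, the odds ratio was 12.9 (Fisher's exact p = 0.0850). Without wild type replicate 2 or Tph1 knockout replicate 3 it was 9.30 and 10.04, and without Tph1 knockout replicate 1 or 4 it was 24.2 and 24.8. Ush1c, from 46195350 to 46238503, rose from 0.135 ± 0.111 to 3.67 ± 1.07 CPM (SD, n = 4 each), and Htatip2, from 49759115 to 49773975, fell by 3.59 ± 0.40 (SE) on the log2 scale, to 1.57 ± 0.888 CPM (SD, n = 4). Gtf2h1, the called gene closest to Tph1, fell by 0.70 ± 0.13 (SE) on the log2 scale. In the list of 32 tested neighbours written before the data were examined, 1 rose and 3 fell, with a median of -0.01 (camera adjusted p = 0.832). Outside 10 Mb and without copies of Ftl1, 92 of the 110 called genes remained, 12 higher and 80 lower, and a refit without those genes called 59.

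**Figure D3:**
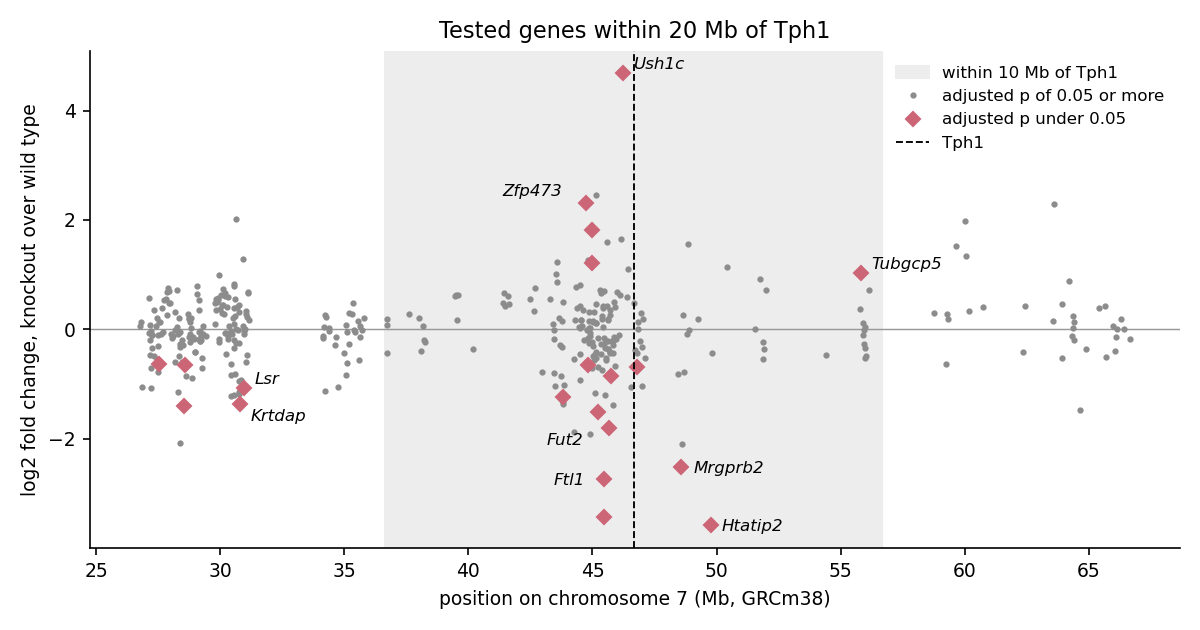
Log2 fold change, knockout over wild type, of each tested gene within 20 Mb of Tph1 against its position on chromosome 7 in GRCm38. Diamonds are genes with an adjusted p under 0.05, the dashed line is Tph1 and the grey band marks 10 Mb on either side, which holds 15 called genes of 186 tested.

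Ftl1, at 45457944 to 45459884 on chromosome 7, fell from 662 ± 84.0 to 99.5 ± 15.6 CPM (SD, n = 4 each; edgeR adjusted p = 0.000315), while near-identical copies on other chromosomes rose. Ftl1-ps1 on chromosome 13, 99.6% identical over 910 bases, rose from 21.3 ± 2.24 to 263 ± 48.7 CPM (log2 fold change 3.63 ± 0.17 SE, edgeR adjusted p = 3.34e-05). The processed pseudogenes Ftl2-ps on chromosome 4 and Ftl1-ps2 on chromosome 10, 98.7% and 97.8% identical, also rose, from at most 14 and 4 counts in a wild-type library to at least 2108 and 130 in a knockout library. RSEM divides shared reads among such copies, so each single value is uncertain. Summed over Ftl1 and its copies, the level was 684 ± 86.0 CPM in wild type and 490 ± 87.3 in knockout, a difference of -0.49 on the log2 scale (exact permutation p = 0.0286) against -2.74 for Ftl1 alone. The ferritin heavy chain gene Fth1 differed by -0.07 (exact permutation p = 0.714).

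**Figure D4:**
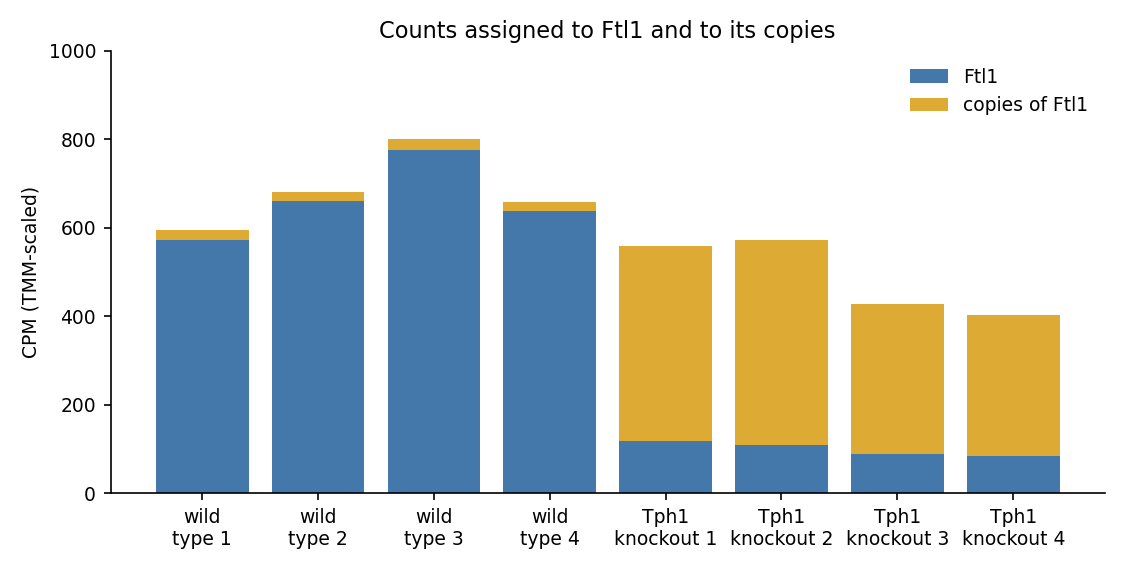
Stacked bars of TMM-scaled CPM assigned to Ftl1 and to its copies in each of the 8 libraries, from 0. Copies hold 3.01% to 3.53% of the sum in wild-type libraries and 79.0% to 81.1% in Tph1 knockout libraries.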

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

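The odds ratio near Tph1, the muscle covariate and the splits over all tested genes and lists were fixed before the data were examined. The tests of hair genes without 1 library, of granular against basal genes, of the summed level of Ftl1 and its copies and of the parents of pseudogenes were chosen after the data were seen. So were the handling covariate and the splits without genes near Tph1.

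In 33 of 458 groups, 1 library lay far from the other 3 of its genotype, over 229 measures. Chance gives such a gap in about 1 in 20 groups, so many of these need no cause. Tph1 knockout replicate 3 held 11 of the 33 and wild type replicate 1 held 7, while each other library held between 1 and 3.

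Ribosomal RNA took 3.08% of counts in wild type replicate 3, against 0.556% to 0.900% in the other wild-type libraries, and 1.51% in Tph1 knockout replicate 1, against 0.497% to 0.660%. Among list levels, wild type replicate 1 was far above the others for spinous genes (8.35) and collagen processing genes (4.87), and wild type replicate 3 was far below for clock genes (5.85) and genes beside Tph1 (3.54). Tph1 knockout replicate 2 was low for thermogenic genes (3.94). Tph1 knockout replicate 3 was high for mast cell (3.05), B cell (2.54) and neutrophil genes (1.21).

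Single genes are given as log2(CPM + 1). Tph1 knockout replicate 3 was high for Sult2b1 (4.55), Tjp3 (5.14), Dgat2l6 (4.69) and Ccl19 (1.67), and low for Ush1c (1.63), Mzb1 (0.61), mt-Co3 (8.21) and Rpl6l (2.08). Wild type replicate 1 was high for Col1a1 (9.85), Col3a1 (9.80), Tyrp1 (2.89), Csf3r (1.90) and Bst2 (4.98). Wild type replicate 2 was low for Crct1 (7.69) and Adamts15 (3.29) and high for Kcnk3 (2.09). Wild type replicate 4 was high for Htr1b (0.62) and low for Krt17 (9.63) and P3h4 (4.61). Tph1 knockout replicate 1 was low for Lrig1 (6.78) and high for P4ha2 (5.37), and Tph1 knockout replicate 4 was low for Oasl2 (3.01) and Sox18 (3.39).

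The list of 37 hair shaft genes had a median log2 fold change of 1.68, with 0 genes called by edgeR and the camera call lost with an estimated correlation (adjusted p = 0.874). Without Tph1 knockout replicate 3 the median was 0.027, so the difference rests on a library that also had the highest melanocyte level (3.84). Libraries at different hair cycle stages within a genotype may account for it. An effect of genotype on the hair cycle stays open and was not tested.

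Ftl1 was lower and its copies higher in knockout skin. Summed over Ftl1 and its copies, the log2 difference was -0.49, much smaller than that of Ftl1 alone, so reads shared between them may account for most of the fall. Called genes were more frequent within 10 Mb of Tph1 (odds ratio 15.3), and besides copies of Ftl1 the 2 processed pseudogenes that rose were copies of genes in that window, against 9 of 603 others (Fisher's exact p = 0.000301). Flanking sequence of another strain carried with the targeted allele is a candidate explanation for both. Regulation of these genes by serotonin loss stays open and was not tested.

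The 90 members of the spinous, granular and barrier lipid lists had a median log2 fold change of -0.87, with 7 called and the 3 camera calls lost with an estimated correlation (adjusted p = 0.534, 0.472 and 0.827). With the adipocyte level, the hair level or 1 surrogate variable as a covariate the median was -0.82, -0.99 and -0.97. With the handling level as a covariate it was -0.28, and with the muscle level it was -0.42. Handling of the tissue or a different share of skeletal muscle may therefore account for part of it. Both levels overlapped between genotypes only through wild type replicate 2, so either covariate also takes up an effect of genotype. The smaller medians thus cannot tell these explanations from genotype. With junction genes included, the 10 called genes had a median of -1.21 and -1.22 under these covariates, against -1.22 without. Their median SE was 0.30 and 0.21, against 0.18 without. Of their calls 9 ended after adjustment over all genes, while all 10 kept an unadjusted p under 0.05 by edgeR. These 10 genes were chosen because they passed without a covariate, which favours genes that vary little within a genotype. Their steady median therefore does not weigh against either covariate. Among the 10, Klk8 and Sult2b1 lie within 10 Mb of Tph1 and also enter the odds ratio near Tph1, so flanking sequence stays open for them. Less epidermis would lower basal genes as well, whose level differed by only -0.056, but it cannot be told apart, since the granular minus basal level differed by -0.81 with exact permutation p = 0.0857, and p = 0.0571 without wild type replicate 2. An effect of the genotype on differentiation stays open beside these and was not tested apart from them.

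No split of the 8 libraries into 4 and 4 other than the real 1 called any gene. The real split called 110 and the highest of the other 34 called 0, so 1 of 35 splits gave as many. That is the smallest share this test can give, so chance is an unlikely source of the count of genes but cannot be excluded. The test also cannot tell genotype from any other difference between the wild-type and knockout libraries. Without genes within 10 Mb of Tph1 and copies of Ftl1 the real split called 59 and the highest other 0, again 1 of 35. For gene lists chance cannot be excluded either, and the real split did not stand out. There 13 of 35 splits called at least the 21 of the real split and the highest other called 32.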

How the results depend on the processing

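The handling covariate, the effective length offsets, the fit without genes near Tph1 and the fit without 2 libraries were chosen after seeing the data. The other alternatives were fixed before.

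The count of 110 changed genes stayed within 1.5 times in 10 of 19 alternatives, from 77 to 156. Each of the 110 genes had the same direction in every alternative that tested it. The DESeq2 Wald test called 984 (341 higher, 643 lower), including all 110, and 1 surrogate variable gave 623 (118 higher, 505 lower). An adjusted p under 0.1 gave 367 (99 higher, 268 lower). With no filter 31 were higher, and with the authors' matrix 59 were lower. The hair covariate gave 44 (10 higher, 34 lower), the muscle covariate 6 (3 higher, 3 lower), the adipocyte covariate 8 (5 higher, 3 lower) and the handling covariate 5 (3 higher, 2 lower). Without genes within 10 Mb of Tph1 and copies of Ftl1 there were 59 (8 higher, 51 lower). This fit removed 18 called genes, and 59 of the 92 others kept their call. Without wild type replicate 2 and Tph1 knockout replicate 3 there were 167 (149 lower). Apart from the 18 removed genes, the cause of these changes was not tested.

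Leaving out 1 library gave 8 genes (without Tph1 knockout replicate 2) to 170 (without Tph1 knockout replicate 3), with 5 to 23 higher and 3 to 147 lower. Each wild-type library but replicate 2 and each knockout library moved the count by over 1.5 times, to 26, 32 and 27 without wild type replicates 1, 3 and 4 and to 19 and 14 without Tph1 knockout replicates 1 and 4. At this depth, with 4 libraries of each genotype, 43% of simulated changes of 1 on the log2 scale were recovered. That share holds for genes with a mean CPM of at least 1, simulated independently of each other.

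Of 21 called lists, camera with an estimated correlation called 0 (3 at an unadjusted p under 0.05) and fry called 1. The other alternatives called 15 to 24 and leaving out 1 library 16 to 21. The exact test of list levels passed 2 lists at an unadjusted p under 0.05. It passed 1 with a pseudocount of 0.5, 3 with a pseudocount of 5 and 1 with CPM by library total. Without 1 library, where the test has fewer assignments, it passed 1 to 7.

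List medians changed sign in 90 of 964 cases, 11 of them in called lists. In 12 cases camera's direction reversed with a call on either side. The hair median was -0.081 with the hair covariate and the muscle median -0.33 with the muscle covariate, by construction. With the handling covariate the medians were 0.090 for proliferation, 0.42 for elastic fibre, 0.64 for proteoglycans, 0.16 for matrix proteases, 0.30 for fibroblasts, -0.27 for fatty acid synthesis and -0.85 for muscle, and the called granular, adipocyte and interferon lists lost their calls with medians of 0.027, 0.076 and 0.075. The interferon median was 0.013 without wild type replicate 1. Without wild type replicate 2 and Tph1 knockout replicate 3 they were -0.089 for hair, -0.52 for melanocytes and -0.34 for endothelium. The cause was not tested.

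Tph1 differed by -0.64 to -0.49 under other scales and by -0.83 (without wild type replicate 2) to -0.44 without 1 library. The odds ratio near Tph1 kept its side of the threshold except with the muscle (18.1), adipocyte (12.9) and handling (22.6) covariates, where few genes were called, and without Tph1 knockout replicate 2 (12.9, Fisher's exact p = 0.0850). Without 1 library it ranged from 9.30 to 24.8. Of 4570 values for genes of the naming rule under alternatives, 4030 kept their side of the threshold, 414 lost it and 126 gained it. The sign changed in 57, none of them called with or without the alternative.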

Other observations

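The lists below were written before the data were examined, while the genes of the last paragraph were chosen after their values were seen. No hypothesis is drawn from them.

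Of 37 hair shaft and inner root sheath genes 0 were called by edgeR, with a median log2 fold change of 1.68 (camera adjusted p = 0.0155, and adjusted p = 0.874 with an estimated correlation). The hair call was lost without wild type replicate 1 (1.78, adjusted p = 0.0888) or Tph1 knockout replicate 3 (0.03, adjusted p = 0.944), with the filter of 1 CPM (0.48, adjusted p = 0.127) and with 1 surrogate variable (0.29, adjusted p = 0.0855), and the median was 2.58 and 2.56 without Tph1 knockout replicates 1 and 4. The hair level per library was 1.77, 1.89, 3.09 and 2.44 in wild type and 1.72, 3.30, 5.09 and 1.97 in knockout. The 5 keratin-associated protein genes had a median of 3.81 (camera adjusted p = 0.453), and 0.25 without Tph1 knockout replicate 3. This list of keratin-associated proteins was called without wild type replicate 4 (4.48) or Tph1 knockout replicate 1 (5.05) or 4 (5.05), with no filter (5.66, adjusted p = 9.44e-08) and with the muscle and adipocyte covariates (5.16 and 4.62, adjusted p = 0.0373 and 0.0213). Of 25 bulge, 10 melanocyte and 20 sebaceous genes 0 were called, with medians of 0.08, 0.56 and 0.09 (camera adjusted p = 0.779, 0.832 and 0.832). The melanocyte median ran from -0.40 (without Tph1 knockout replicate 3) to 0.93 when 1 library was left out, and the bulge median from -0.020 to 0.16. The sebaceous list was called lower without Tph1 knockout replicate 3 (-0.60, adjusted p = 0.000564), with a median of up to 0.34 without another library, and it was called lower with the hair covariate (-0.40, adjusted p = 0.0461). Without wild type replicate 2 and Tph1 knockout replicate 3 the melanocyte and sebaceous lists were called lower (-0.52 and -0.59, adjusted p = 0.0387 and 0.00213).

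Of 12 mast cell genes 1 fell, Mrgprb2, which lies within 10 Mb of Tph1, with a median of -0.74 (camera adjusted p = 0.00903, and adjusted p = 0.827 with an estimated correlation). The call was lost without genes within 10 Mb of Tph1 (-0.64, adjusted p = 0.144), and without wild type replicate 1 (-0.01) or Tph1 knockout replicates 1 (-0.54) or 2 (-0.42), and the median was -1.57 without Tph1 knockout replicate 3. The mast cell call was also lost with the muscle, adipocyte and handling covariates (-0.18, -0.35 and -0.11, adjusted p = 0.260, 0.0605 and 0.675). Of 21 T and natural killer cell genes 0 were called, with a median of -0.34 (camera adjusted p = 0.0155, and adjusted p = 0.827 with an estimated correlation). The T and natural killer cell call was lost without Tph1 knockout replicate 1 (-0.06) and with the muscle and adipocyte covariates (-0.082 and -0.11, adjusted p = 0.145 and 0.122), and the median was -0.58, -0.87 and -0.19 without wild type replicate 4 and Tph1 knockout replicates 3 and 4. Of 31 macrophage and dendritic cell genes 0 were called, with a median of -0.55 (-0.87 without Tph1 knockout replicate 3; camera adjusted p = 2.90e-05, and adjusted p = 0.827 with an estimated correlation). The 5 B cell genes and 4 neutrophil genes had medians of 0.48 and -1.02 (camera adjusted p = 0.918 and 0.275), and from -0.29 to 0.87 and from -1.84 to -0.37 without 1 library. The neutrophil list was called without wild type replicate 4 (-1.38) or Tph1 knockout replicate 3 (-1.84), and with no filter (-0.82, adjusted p = 0.00943).

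Of 22 inflammatory cytokine and chemokine genes 0 were called, with 3 lower when adjusted over the list alone and a median of -0.86 (camera adjusted p = 1.60e-05, and adjusted p = 0.534 with an estimated correlation). The call was lost with the handling covariate (-0.081, adjusted p = 0.618). The inflammatory level was 2.86 ± 0.42 (SD, n = 4) in wild type and 2.25 ± 0.12 in knockout, lower in 4 of 4 knockout libraries (exact permutation p = 0.0286, adjusted p = 0.429). That separation was narrow, with wild type replicate 2 at 2.427 and Tph1 knockout replicate 3 at 2.415. Of 27 interferon-stimulated genes 0 were called, with a median of -0.58 (camera adjusted p = 0.000615, and adjusted p = 0.827 with an estimated correlation), and the median was 0.01 without wild type replicate 1 (adjusted p = 0.279). The interferon call was also lost with the handling covariate (0.075, adjusted p = 0.618).

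The lists of 25 endothelial, 18 pericyte, 18 Schwann cell, 13 erythrocyte and platelet and 20 clock genes had 0 called genes and medians of 0.06, 0.11, -0.03, 0.29 and 0.12. Without 1 library the medians of the endothelial, pericyte, Schwann cell, erythrocyte and clock lists ran from -0.19 to 0.28, -0.0045 to 0.22, -0.044 to 0.10, 0.077 to 0.57 and 0.044 to 0.22. With all 8 libraries their camera adjusted p were 0.918, 0.186, 0.918, 0.763 and 0.490, and the pericyte list was called without wild type replicate 1 (0.21, adjusted p = 0.0488). The endothelial list was called higher with the muscle and handling covariates (0.38 and 0.69, adjusted p = 0.0156 and 0.000270) and lower without wild type replicate 2 and Tph1 knockout replicate 3 (-0.34, adjusted p = 0.00985).

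Tmem254a, Plac9b and Tmem254b, between 25923300 and 26203369 on chromosome 14, had log2 fold changes of -1.60, -2.25 and -1.48, and the pseudogenes Gm5859 and Gm17081, at 42236859 and 42239725 on chromosome 4, also fell, Gm5859 by 4.52.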
